A study of Mus musculus with 2 samples.

How the data were processed

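Small RNA was sequenced from exosomes released by mouse bone marrow-derived macrophages. Per the labels' protocols, marrow cells of C57BL/6 mice were grown with M-CSF at 10 ng/mL for 7 days and then polarised for 1 day with 20 ng/mL of a cytokine, IFN-γ for the M1 state or IL-4 for the M2 state. The cells were then held in serum-free medium for 2 days, and exosomes were collected from that medium by differential centrifugation, filtration and ultracentrifugation. RNA was extracted with Trizol, and 500 ng went into a NEBNext small RNA library kit. The series holds 2 libraries, 1 from M1 exosomes and 1 from M2 exosomes. There are no replicates, so no value has a replicate error and no test of the conditions was made.

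Bowtie2, bedtools and the mm10 build are named in the submitters' processing notes, without versions or roles. How reads were assigned to mature miRNAs, how reads matching several copies were handled, whether strand was used and how values were normalized are not given in the sources used here. The values the authors deposited are on a log2 scale, 1 per mature miRNA, and both files list the same 1976 miRNAs. The scale was settled from the values. After conversion to a linear level (2 to the power of the value, minus 1) the lowest levels fell on evenly spaced steps, and the step was taken as the worth of 1 read. In M1 exosomes the step was 0.80 units, seen in 174 miRNAs whose M2 value lay below 1 step, of which 100% were whole multiples within 0.1 step. In M2 exosomes the step was 1.22 units, seen in 128 miRNAs listed at 0 in M1, of which 96.1% were whole multiples within the same tolerance. A low value of a given size thus rests on more reads in the M1 library. The steps are known only at low levels, and the total number of reads is unknown. The minimum of 10 units used here lay near 12.5 reads in M1 exosomes and 8.18 reads in M2 exosomes. A level listed at 0 allows up to 3 reads, or 2.40 units in M1 exosomes and 3.67 units in M2 exosomes, for counting error only.

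The low values of one library moved with the value in the other. The M2 value of 175 miRNAs lay between 0.03 and 0.135, below the worth of 1 read, and rose with the M1 value. The deposited values of the 2 libraries were therefore treated as normalized together, in a way that depends on level. The median log2 ratio of M1 over M2 was 0.04 over the miRNAs compared. A change shared by most miRNAs could not be seen if such a step centred the ratios, and every difference is relative to that median. Read counts at higher levels were not reconstructed, so intervals on single values are not given.

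The ratio reported for each miRNA is the difference of the deposited log2 values, M1 minus M2. It is on the log2(level + 1) scale and understates differences of low miRNAs. A miRNA was compared if its level reached 10 units in at least 1 library. It was counted as different if the log2 ratio was at least 1 in size, which is 2-fold. The planned comparison allowed for counts or for normalized values, with a minimum of 10 CPM for the latter. The values are neither counts nor CPM, so the rule for normalized values was used with its minimums read as units of the deposited scale, and the TMM factors, counting intervals and thinning planned for counts were not run.

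The comparison, the naming rule and 24 lists of mature miRNAs were fixed before the data were examined (polarisation-associated, families and clusters, markers of other cell types, and entries that overlap rRNA or tRNA). The phrase entries that overlap rRNA or tRNA is the name of a list, and the match of its members to rRNA or tRNA was not checked. A list with at least 3 compared members was described by its median ratio and by the percentile of that median among 10000 random lists of the same size matched on mean level in 10 bins. The percentile describes these 2 libraries and is not a test of polarisation. The rule for miRNAs named in the text takes the 10 most abundant of each library, the 10 largest ratios each way among miRNAs with a mean of at least 100 units, up to 4 members per list at that mean, and 6 miRNAs whatever their level (miR-155-5p, miR-146a-5p, miR-223-3p, miR-21a-5p, miR-378a-3p and miR-511-3p), 72 in all. Other miRNAs named in the text are list members that make up a small count or a contrast within a list, and were chosen after their values were seen.

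Hairpin positions come from the RefSeq gene table for GRCm38.p6, or from GENCODE M21, which is also on GRCm38, the assembly called mm10. Overlap with other genes comes from GENCODE M21. Of the 337 miRNAs compared, 86.4% had a hairpin arm sequence there, taken as the 5′ or 3′ side of the hairpin, for the GC check. The procedure was tested on simulated libraries built from the real levels, with the read steps of the low values applied at all levels. Among the 337 miRNAs, 200 were changed 4-fold. Over 20 runs the procedure recovered 96.8% of them, with 0 called in the wrong direction. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives covered the scaling, the minimum level, the pseudocount, the fold threshold, the entries that overlap rRNA or tRNA and a GC correction.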

Results

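The series compared the miRNA content of exosomes from macrophages polarised with IFN-γ (M1) or IL-4 (M2), with 1 library from each. Exosomes are small vesicles that cells release and that carry RNA to other cells. Bone marrow-derived macrophages are primary macrophages grown from marrow with the growth factor M-CSF. Of the 1976 mature miRNAs listed, 618 were above 0 in M1 exosomes and 747 in M2 exosomes, and 1229 were listed at 0 in both. Of the 747 in M2 exosomes, 175 had values below the worth of 1 read, and 572 remain without them, so these numbers do not order the libraries. The level reached 10 units for 288 miRNAs in M1 exosomes and for 295 in M2 exosomes, and 246 reached it in both. Levels summed to 686353 units in M1 exosomes and 734637 units in M2 exosomes. Total read counts were not analysed here. Nothing below has a replicate error, so each difference compares 2 libraries and not the 2 conditions.

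Both libraries were dominated by a few miRNAs, and largely by the same ones. The 10 most abundant miRNAs held 65.3% of the summed level in M1 exosomes and 69.0% in M2 exosomes, and 9 of the 10 were shared. miR-146a-5p, which is induced by NF-κB and dampens its signalling, was the most abundant in M1 exosomes, with 17.6% of the level against 6.89% in M2 exosomes. It was followed there by miR-122-5p with 8.71%, a miRNA best known from hepatocytes. In M2 exosomes let-7j held 10.9%, miR-99a-5p 10.8%, miR-148a-3p 9.56% and let-7f-5p 7.65%. The corresponding shares in M1 exosomes were 3.43%, 5.78%, 4.24% and 1.81%. miR-27b-3p, miR-221-3p, let-7i-5p, miR-21a-5p and miR-10a-5p were among the 10 most abundant in both. Across the 337 miRNAs compared, the Spearman correlation of the libraries was 0.86. It is a correlation across miRNAs, which are not independent replicates.

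Among these 337 miRNAs, 88 were at least 2-fold higher in M1 exosomes, 77 were at least 2-fold higher in M2 exosomes and 172 lay within 2-fold. The standard deviation of the log2 ratio over miRNAs was 1.59. Of the 154 with a mean level of at least 100 units, 33 were higher in M1 exosomes, 31 were higher in M2 exosomes and 90 lay within 2-fold. In 100 simulations of 2 unchanged libraries at the read worth seen in the low values, counting noise alone gave at most 16 such calls in both directions together, against 165 observed. It gave 0 calls at a mean of 100 units or more, against 64 observed. Those simulations leave out variation between cultures, exosome preparations and libraries, which 1 library per group cannot measure. They also apply the read worth of the low values at all levels, although it is known only at low ones.

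**Figure D1:**
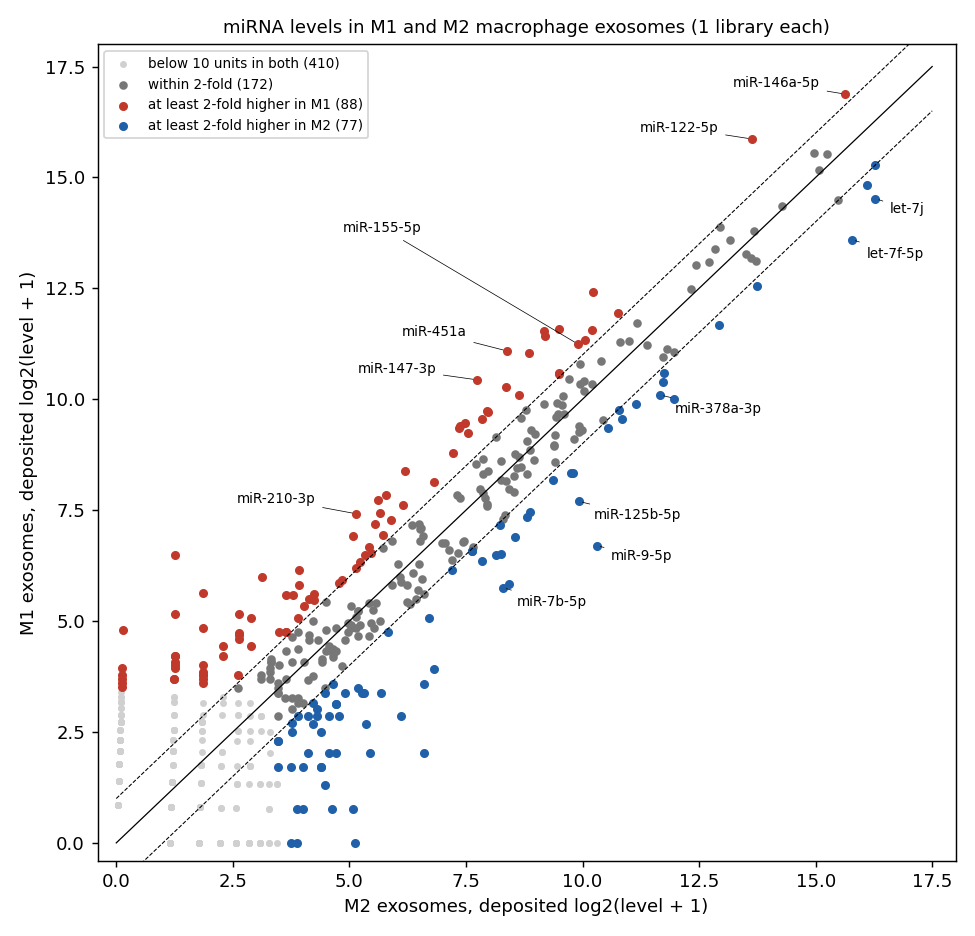
Deposited log2(level + 1) of each miRNA above 0 in either library, M2 exosomes on the x axis and M1 exosomes on the y axis; the solid line marks equality and the dashed lines a 2-fold difference, and each point is 1 miRNA in 1 library per group. The 88 red points are at least 2-fold higher in M1 exosomes, the 77 blue points at least 2-fold higher in M2 exosomes, and miR-146a-5p and miR-122-5p are the highest red points.

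Among miRNAs with a mean of at least 100 units, miR-451a, miR-147-3p and miR-486a-5p had the largest excess in M1 exosomes. Larger ratios occurred at lower levels, up to a log2 ratio of 5.24 for miR-12188-5p. miR-451a, an erythroid miRNA, was 6.60-fold higher, at a log2 value of 11.09 in M1 exosomes and 8.37 in M2 exosomes. Its hairpin lies between annotated genes at chromosome 11, 78073170 to 78073241 (GRCm38, as all positions here, which are those of hairpins and not of mature arms). miR-147-3p, which Toll-like receptor signalling induces in macrophages, was 6.54-fold higher, at 10.44 against 7.73. Its hairpin lies at chromosome 2, 122640803 to 122640881, in an exon of AA467197. miR-486a-5p and miR-486b-5p were 5.13-fold and 4.68-fold higher. Their hairpins overlap on opposite strands in an intron of Ank1 at chromosome 8, 23142555 to 23142682. The values of the 2 entries were nearly equal, at 11.53 and 11.43 in M1 exosomes and 9.17 and 9.20 in M2 exosomes. The 2 entries may hold the same reads, so they may be 1 observation. miR-210-3p, which is induced by hypoxia, was 4.86-fold higher, at 7.42 against 5.14. miR-122-5p was 4.72-fold higher, at 15.87 against 13.63. Its hairpin lies at chromosome 18, 65248861 to 65248926, where the hairpin of miR-122b overlaps it, and miR-122b-3p was 4.57-fold higher. miR-99b-5p and miR-125a-3p, from neighbouring hairpins in Spaca6 on chromosome 17, were 4.57-fold and 4.58-fold higher. miR-409-3p of the imprinted Dlk1-Dio3 region was 4.31-fold higher.

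Among miRNAs with a mean of at least 100 units, the largest excess in M2 exosomes was that of miR-9-5p, which was 12.2-fold higher, with a log2 value of 10.30 against 6.70 in M1 exosomes. At lower levels the log2 ratio reached -4.58 for miR-378a-5p, and miR-6356 was listed at 0 in M1 exosomes against 5.12. The mature form of miR-9-5p comes from 3 hairpins on chromosomes 3, 13 and 7, which the values do not separate. Members of the miR-378 family, whose first member lies in an intron of Ppargc1b at chromosome 18, 61397835 to 61397900, were also higher in M2 exosomes. miR-378d was 5.99-fold higher, miR-378b 3.14-fold and miR-378a-3p 2.96-fold. Reads of these family members may be split by the counting, so the single values are uncertain. miR-7b-5p was 5.80-fold higher and miR-125b-5p 4.68-fold higher. let-7f-5p was 4.53-fold higher, let-7d-5p 3.84-fold and let-7j 3.39-fold. miR-152-3p was 3.33-fold higher and miR-27a-5p 3.11-fold. miR-148a-3p, which has the same seed as miR-152-3p, was 2.41-fold higher, at 16.10 against 14.83.

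The list of miRNAs associated with M1 polarisation was higher in M1 exosomes. Of its 6 compared members 4 were at least 2-fold higher there, 1 was higher in M2 exosomes and 1 lay within 2-fold, with a median log2 ratio of 1.64 (SD over members 2.40). That median stood at the 97.54th percentile of random lists, equal to the upper bound of their central 95%. miR-155-5p, a central inflammatory miRNA of macrophages whose hairpin lies in an exon of Mir155hg at chromosome 16, 84714140 to 84714204, was 2.55-fold higher, at 11.25 against 9.90. The other members higher in M1 exosomes were miR-147-3p, miR-451a and miR-127-3p, of which the last 2 also belong to the erythroid and Dlk1-Dio3 lists. miR-9-5p was the member higher in M2 exosomes, and miR-181a-5p had a log2 ratio of 0.15. miR-204-5p was listed at 0 in both libraries, and miR-155-3p was below the minimum.

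The list associated with M2 polarisation did not stand apart from random lists. Its 8 compared members had a median log2 ratio of -0.39 (SD 1.84), at the 15.5th percentile, with 2 at least 2-fold higher in M2 exosomes, 2 at least 2-fold higher in M1 exosomes and 4 within 2-fold. miR-378a-3p, which IL-4 induces in macrophages, was one of those higher in M2 exosomes. The other was miR-511-3p, from an intron of the M2 marker gene Mrc1 at chromosome 2, 14261003 to 14261081, which was 2.26-fold higher but only just reached the minimum, at 3.47 against 2.29. miR-223-3p, an abundant myeloid miRNA, had a log2 ratio of -0.69. The members higher in M1 exosomes were miR-145a-5p, with a log2 ratio of 3.91, and miR-146a-3p, with 2.00. Both had M2 levels below the 3.67 units that 3 reads are worth there, so the size of these ratios is uncertain.

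The NF-κB feedback list was split. Of its 6 compared members 3 were at least 2-fold higher in M1 exosomes and 3 lay within 2-fold, with a median of 0.41 (SD 1.04) at the 82.6th percentile. miR-146a-5p, from chromosome 11, 43374397 to 43374461, was 2.38-fold higher in M1 exosomes. Its paralogue miR-146b-5p had a log2 ratio of -0.62. miR-21a-5p had a log2 ratio of -0.99, next to the 2-fold line, while its low passenger strand miR-21a-3p had 1.06. The myeloid and haematopoietic list was also mixed, with 2 of 8 members at least 2-fold higher in M1 exosomes, 1 in M2 exosomes and a median of -0.11 (SD 1.07). miR-22-3p was 2.42-fold higher in M1 exosomes. miR-191-5p and miR-342-3p lay within 2-fold, at log2 ratios of 0.50 and 0.45.

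**Figure D2:**
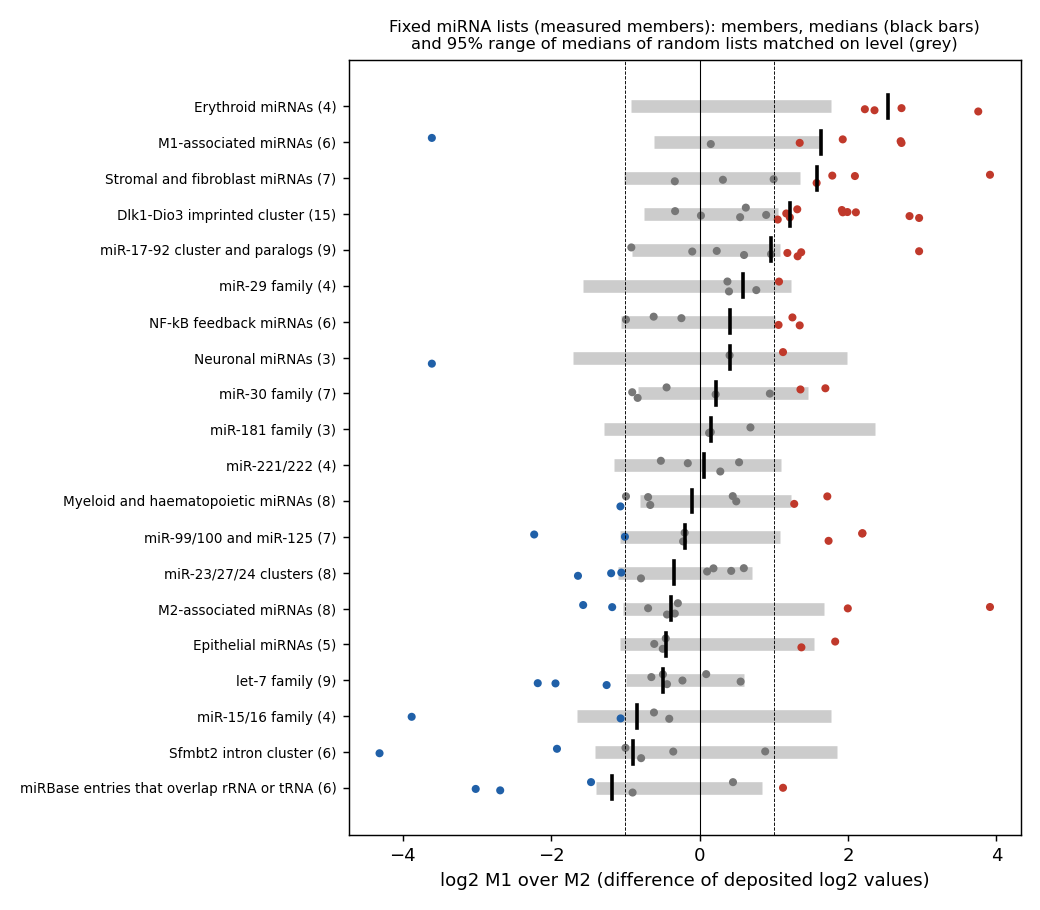
log2 ratio of M1 over M2 exosomes for the compared members of each fixed list with at least 3 of them; points are miRNAs, red and blue points are at least 2-fold higher in M1 and in M2 exosomes, black bars are list medians, and grey bars are the central 95% of medians of 10000 random lists matched on level. The erythroid median of 2.54 lies farthest to the right, followed by the M1-associated, stromal and Dlk1-Dio3 medians.

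In the let-7 family 3 of 9 compared members were at least 2-fold higher in M2 exosomes and 0 in M1 exosomes, with a median of -0.49 (SD 0.91) at the 20.2nd percentile. let-7i-5p, let-7g-5p and let-7c-5p had log2 ratios of 0.09, -0.23 and -0.44. In the list of miR-99, miR-100 and miR-125, 3 of 7 members were at least 2-fold higher in M1 exosomes and 2 in M2 exosomes, with a median of -0.20 (SD 1.72) at the 33.0th percentile. The members higher in M1 exosomes were miR-99b-5p, miR-99b-3p and miR-125a-3p, from 1 locus on chromosome 17, whose other arm miR-125a-5p had a log2 ratio of -0.20. Those higher in M2 exosomes were miR-99a-5p, 2.01-fold, and miR-125b-5p. miR-100-5p had a log2 ratio of -0.22. In the clusters of miR-23, miR-27 and miR-24, 3 of 8 members were at least 2-fold higher in M2 exosomes and 5 lay within 2-fold, with a median of -0.34 (SD 0.85) that turned to 0.10 with a minimum of 100 units. miR-23a-3p was 2.28-fold higher in M2 exosomes, while miR-27a-3p, miR-27b-3p and miR-24-3p had log2 ratios of 0.43, 0.60 and 0.10.

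The miR-17-92 cluster and its paralogs, which promote proliferation, had 4 of 9 members at least 2-fold higher in M1 exosomes and 0 in M2 exosomes, with a median of 0.96 (SD 1.09) at the 94.3rd percentile. miR-106b-3p was 2.27-fold higher, and miR-92a-3p, miR-25-3p and miR-93-5p had log2 ratios of 0.96, 0.60 and 0.23. The 2 members below 0 were miR-17-5p, at -0.10, and miR-20a-5p, at -0.92. The calls include both arms of miR-106b, and also miR-363-3p, whose M2 level lay below that of 3 reads. The 4 members of the list of miR-221 and miR-222 lay within 2-fold, with a median of 0.06 (SD 0.47), which was -0.0078 when scaled to the total without the 10 most abundant miRNAs, and log2 ratios of 0.28 for miR-221-3p and 0.53 for miR-222-3p. The 3 compared members of the miR-181 family also lay within 2-fold, with a median of 0.15 (SD 0.32). In the miR-29 family 1 of 4 members was at least 2-fold higher in M1 exosomes, with a median of 0.58 (SD 0.33), and miR-29a-3p had 0.38. In the miR-30 family 2 of 7 were higher in M1 exosomes, with a median of 0.22 (SD 1.06). miR-30a-5p was 2.57-fold higher and miR-30d-5p had a log2 ratio of 0.95. In the miR-15/16 family 2 of 4 were higher in M2 exosomes, with a median of -0.84 (SD 1.62), and miR-16-5p had -0.41. The calls were miR-322-5p, listed at 0 in M1 exosomes, and miR-15a-5p, at -1.06. With the minimum required in both libraries the median of this family was -0.61. The list of the Sfmbt2 intron cluster was set by name, and its compared member miR-466i-5p has its hairpin on chromosome 13. In this list 2 of 6 were higher in M2 exosomes, with a median of -0.89 (SD 1.76), and miR-669c-5p had -0.79. The calls include miR-467a-5p, whose M1 level of 0.69 units lay below the worth of 1 read.

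miRNAs of the imprinted Dlk1-Dio3 region on chromosome 12 were higher in M1 exosomes. Of the 15 compared members of the list, 10 were at least 2-fold higher there, 0 were at least 2-fold higher in M2 exosomes and 5 lay within 2-fold. The median log2 ratio was 1.22 (SD 0.95), at the 99.1st percentile. The calls include miR-409-5p, miR-410-3p and miR-431-5p, whose M2 levels lay below that of 3 reads, so the size of their ratios is uncertain. With the minimum required in both libraries the list median was 1.19. miR-127-3p, from an exon antisense to the imprinted gene Rtl1 at chromosome 12, 109592846 to 109592915, was 3.81-fold higher, at 10.28 against 8.35. miR-379-5p was 3.98-fold higher, at 9.47 against 7.48. miR-409-3p was 4.31-fold and miR-382-5p 2.49-fold higher. The summed level of the list was 0.43% of the M1 library and 0.12% of the M2 library. Between positions 109580233 and 109743795, 22 compared miRNAs were annotated, of which 16 were at least 2-fold higher in M1 exosomes and 21 had a ratio above 0. Markers of stromal and fibroblast cells, which also express this region, were higher in the same library, with a median of 1.58.

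**Figure D3:**
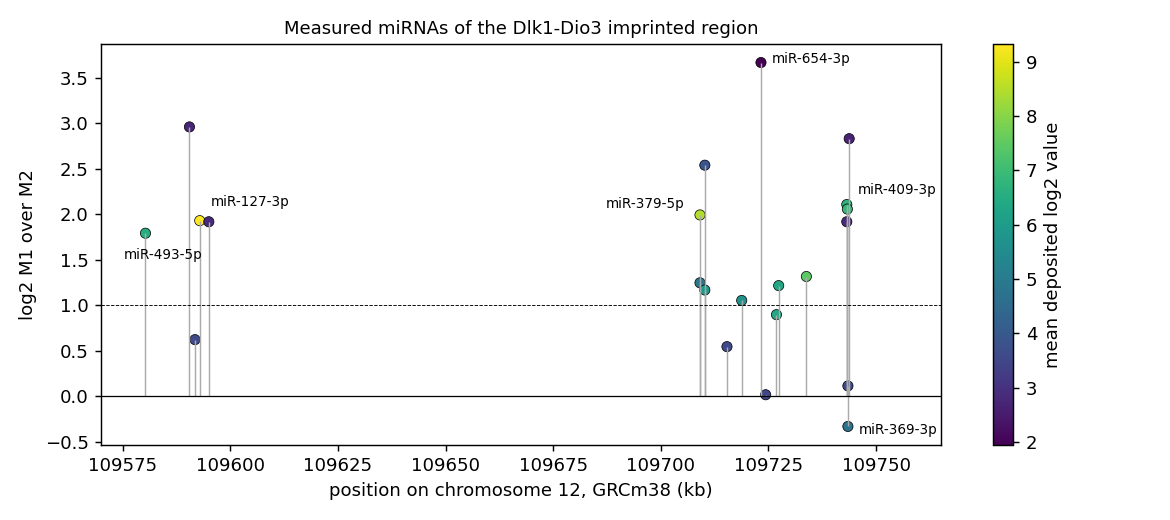
log2 ratio of M1 over M2 exosomes against the position on chromosome 12 (GRCm38, kb) for the 22 compared miRNAs of the Dlk1-Dio3 region; each point is 1 mature miRNA, its colour is the mean deposited log2 value, and the dashed line marks 2-fold. Of the points, 21 lie above 0, and miR-369-3p, at -0.33, lies below it.

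Among markers of cell types other than macrophages, the erythroid and stromal lists were higher in M1 exosomes. The 4 compared erythroid miRNAs were each at least 2-fold higher in M1 exosomes, with a median of 2.54 (SD 0.69) at the 99.98th percentile. They are miR-451a, miR-144-5p with a log2 ratio of 3.76 and an M2 level below that of 3 reads, and the overlapping pair of miR-486 entries. That pair may hold the same reads. The hairpins of miR-144, at 78073005 to 78073070, and miR-451a are neighbours on chromosome 11, so the 4 entries come from 2 loci, while the random lists draw single miRNAs without regard to locus. Of the liver list only miR-122-5p was compared, and it was higher in the same library. Of the 7 compared stromal and fibroblast miRNAs 4 were at least 2-fold higher in M1 exosomes, at the 98.2nd percentile. The calls include miR-145a-5p, whose M2 level lay below that of 3 reads. Both arms of miR-199a and of the related miR-199b are on this list, so its members are not independent. miR-10b-5p was 4.27-fold higher and miR-199a-3p 3.46-fold, miR-199b-5p lay next to the 2-fold line at 1.00, and miR-143-3p, also on this list, had -0.33. The endothelial miR-126a-3p had a log2 ratio of 0.71. Of 5 compared epithelial miRNAs 2 were at least 2-fold higher in M1 exosomes and 0 in M2 exosomes, with a median of -0.46 (SD 1.17) that turned to 0.46 with the minimum required in both libraries. In the neuronal list miR-9-5p was at least 2-fold higher in M2 exosomes, miR-129-5p, with a log2 ratio of 1.12, was at least 2-fold higher in M1 exosomes, and miR-128-3p had 0.40, which was the median (SD 2.55). The lymphocyte miR-150-5p had -1.70 at a low level, and the muscle miRNAs miR-133b-3p and miR-206-3p had -3.12 and -0.27. The M1 level of miR-133b-3p lay below that of 3 reads, so the size of its ratio is uncertain. The list of entries that overlap rRNA or tRNA had a median of -1.18 (SD 1.66) at the 5.26th percentile, with 3 of 6 higher in M2 exosomes and 1 in M1 exosomes. The calls higher in M2 exosomes include miR-5126, whose M1 level lay below that of 3 reads. Of the members of this list, miR-6240 and miR-5099 lay between annotated genes and miR-2137 in an intron of Zfp185. Of the 20 lists with a median, the erythroid, Dlk1-Dio3 and stromal lists, 3 in all, lay outside the central 95% of random lists, and the M1-associated median equalled the upper bound. Chance gives 1 for unlinked members, but members of several lists share a locus and some lists share members, so that number is a rough guide.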

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

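The minimum required in both libraries, division of each library by its sum, the unweighted trimmed mean of log ratios, the restriction to miRNAs with an arm sequence and the GC correction were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and no library could be left out. The numbers of miRNAs called depended on the minimum level. They were 201 higher in M1 exosomes and 229 higher in M2 exosomes with no minimum, and 37 and 33 with a minimum of 100 units. With the minimum required in both libraries, which leaves out miRNAs low in 1 of them, they were 55 and 37. Lower minimums add miRNAs of a few reads, whose ratios carry large counting error. With a minimum of 1 unit, 517 miRNAs were detected in M1 exosomes and 572 in M2 exosomes. A read is worth 0.80 units in M1 exosomes and 1.22 units in M2 exosomes, so that minimum leaves out single reads in M1 exosomes only, where 618 miRNAs were above 0. With 100 units the numbers were 149 and 144. The Spearman correlation across miRNAs was 0.75 with no minimum. The 4 other scalings moved all log2 ratios alike, by between -0.07 and 0.10. They gave 85 to 94 miRNAs higher in M1 exosomes and 66 to 83 higher in M2 exosomes. Of 288 values of the 72 named miRNAs under these scalings, 281 stayed on their side of the 2-fold line, 6 crossed it upward, 1 crossed it downward and 0 changed sign from a call. Those that crossed it are miR-21a-5p, miR-99a-5p, miR-199b-5p, miR-92a-3p and miR-30d-5p. Shifts of -0.07 to 0.10 can move only ratios close to the line, and no scaling that depends on level was tried. With a pseudocount of 10 the counts were 66 and 57, and among miRNAs with an arm sequence they were 78 and 64 before and 78 and 61 after removal of the GC trend. That trend had a slope of 0.12 in log2 ratio per 10 percentage points of GC. At a mean of at least 100 units the slope was 0.45, and counts and named ratios after removal of this steeper trend were not computed. All 132 list medians computed under other scalings, higher minimums or the GC correction stayed within 1 SD of the list's members from the reported median, which is a wide margin, and 3 changed sign. The median of the miR-23, miR-27 and miR-24 clusters was 0.10 with a minimum of 100 units, the epithelial median was 0.46 with the minimum in both libraries, and the median of miR-221 and miR-222 was -0.0078 when scaled to the total without the 10 most abundant miRNAs. The share of the 10 most abundant miRNAs without entries that overlap rRNA or tRNA also moved by less than 5 percentage points. TMM, the counting intervals and the thinning to equal depth were not run, since the values are not counts. Summing of repeated names was not run, since no name is repeated.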

Other observations

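The tests on levels near the floor, on stromal miRNAs, on reads shared within let-7, on GC content at a mean of at least 100 units and on genomic clusters without chromosome 12 were chosen only after results had been seen, and so were the miRNAs named here that the rule did not name. Some miRNAs on no fixed list were higher in M2 exosomes together with relatives, a choice made without a tally of other families. miR-148 and miR-152 had log2 ratios of -1.27 for miR-148a-3p, -1.29 for miR-148b-3p and -1.74 for miR-152-3p. miR-26a-5p and miR-26b-5p had -1.24 and -1.17, and miR-7a-5p and miR-7b-5p had -1.34 and -2.54. miR-374b-5p had -1.20, while its relatives miR-374c-5p and miR-374c-3p had -0.50 and -0.61. In M1 exosomes miR-423-3p had a log2 ratio of 1.46, miR-503-5p 1.47 and the epithelial miR-200a-3p 1.83. Neighbours did not all share that direction. Near miR-200a on chromosome 4, miR-200b-3p had -0.61 and miR-429-3p -0.50. Near miR-503 on chromosome X, miR-351-5p had -1.045, while the arms of miR-322 had 0.83 (3p) and -3.88 (5p). Among the 337 miRNAs compared, 3 were listed at 0 in M1 exosomes, with M2 log2 values of 5.12 for miR-6356, 3.88 for miR-322-5p and 3.75 for miR-3079-5p. Another 6 had an M2 value below the worth of 1 read, with M1 log2 values of 4.81 for miR-145a-3p, 3.94 for miR-7021-5p, 3.79 for miR-654-3p, 3.70 for miR-935, 3.61 for miR-3473g and 3.51 for miR-26b-3p.

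The erythroid and liver miRNAs were higher in M1 exosomes, with a median log2 ratio of 2.36 over 5 members. For the 4 members with an arm sequence, the tables argue against a linear GC trend as the whole cause. Its removal moved their median from 2.30 to 2.20 (SD 0.86). The steeper trend at a mean of at least 100 units moved that of 3 members from 2.24 to 1.75 (SD 0.39). Those 3 are miR-122-5p and the overlapping miR-486 pair, which may be 1 observation, so the values rest on few loci. The other member was miR-144-5p, with an M2 level below that of 3 reads. miR-451a had no arm sequence and is not covered. Serum or blood RNA carried over from the medium used before the serum-free step is a candidate source that stays open. Other miRNAs known as abundant in plasma (miR-423-5p, miR-320-3p, miR-484, miR-185-5p, miR-192-5p and miR-194-5p) had a median of 0.35 (SD 0.38) with 0 of 6 at least 2-fold higher in M1 exosomes, which lies between the median of 1 that carry-over predicted and the bound of 0 set to exclude it. Polarisation stays open as well, as untested, since each state has 1 library.

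The miRNAs of the Dlk1-Dio3 region were higher in M1 exosomes, and 7 of 7 compared miRNAs of the region that were not on the list also had a ratio above 0. These 7 are not independent of the list, since miR-379-3p, miR-411-3p and miR-369-5p are the other arms of listed hairpins. In addition, miR-654-3p and miR-432 had M2 levels below that of 3 reads, with M2 log2 values of 0.12 and 1.86. The tables argue against GC content, with a median over 15 members of 1.27 (SD 0.91) after removal of its trend against 1.22 before, and 1.89 against 1.96 for the 4 members at a mean of at least 100 units. They also argue against levels near the floor for those 4 members, which had a median of 1.96 and a range of 1.32 to 2.11. The listed calls of miR-409-5p, miR-410-3p and miR-431-5p, with M2 levels below that of 3 reads, are not covered. RNA of stromal cells stays open, since the stromal list had a median of 1.58 (SD 1.37), but 1 of its 5 members at a mean of at least 100 units, miR-143-3p, had -0.33. Polarisation and carry-over from serum stay open too and were not tested for this region.

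The let-7 family, let-7j included, held 14.6% of the level in M1 exosomes and 28.5% in M2 exosomes. Most of that difference lay in let-7j, at 3.43% in M1 and 10.9% in M2 exosomes, and let-7f-5p, at 1.81% and 7.65%. The fixed list, which leaves out let-7j, held 11.2% in M1 exosomes and 17.7% in M2 exosomes. Sharing that only moves reads between near-identical members leaves the sum unchanged. The summed level of the 11 entries had a log2 ratio of -1.06, which argues against that form of sharing as the cause. Reads counted in several entries would not leave the sum unchanged. How such reads were handled is not given, so an effect of repeated counting on the sum stays open. For GC content, the log2 ratio had a Spearman rho of 0.0783 with arm GC over 282 miRNAs outside let-7, below the bound of 0.1 set to exclude it, and removal of that trend left the let-7 median at -0.50 (SD 0.86), against -0.49 before and a bound of -0.5 to exclude it. These bounds rest on a trend weaker than that at means of at least 100 units, where all 9 compared let-7 members lie, rho outside the family was 0.28 and removal of the trend moved the median to -0.41 (SD 0.73). The corrections apply to the median of those 9 members, which stood at the 20.2nd percentile of random lists, and not to the summed level, since let-7j has no arm sequence, so GC content stays open for the sum, as does polarisation, which was not tested.

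One hypothesis was that the ratio follows the hairpin. Arms were paired by name. Over 68 such pairs the median absolute difference of log2 ratios between arms was 0.77, against 1.34 in random pairs matched on level. That difference stood at the 0.05th percentile of 10000 random sets. Some pairs are not 1 separate hairpin, since miR-199a has 2 hairpins, miR-669a has 12, and miR-486a and miR-486b overlap. The arms were thus more alike than random pairs, although 26 of the 68 pairs had ratios of opposite sign. Among these, miR-142a-5p had a log2 ratio of 1.72 and miR-142a-3p -1.07, miR-30e-5p 1.70 and miR-30e-3p -0.91, and let-7d-5p -1.94 and let-7d-3p 1.09. A hypothesis that the ratio follows the genomic cluster was not settled. miRNAs of different hairpins within 10000 bases were closer than random pairs, at the 0.39th percentile over 150 pairs of 104 miRNAs. Without chromosome 12 the percentile was 12.7 over 97 pairs of 83 miRNAs. A miRNA can occur in several of these pairs, while the random sets drew each pair separately, so both percentiles are a rough guide.

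Some entries whose hairpins overlap in the genome had nearly the same offset in both libraries. miR-122-5p exceeded miR-122b-3p by 3.46 in M1 exosomes and 3.41 in M2 exosomes on the log2 scale. miR-486a-5p exceeded miR-486b-5p by 0.10 in M1 exosomes, and the difference was -0.03 in M2 exosomes. Other overlapping pairs differed more, such as miR-142a-5p, which exceeded miR-142b by 6.18 in M1 exosomes and 4.37 in M2 exosomes.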
